A study of Arabidopsis thaliana with 5 samples.

How the data were processed

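Inflorescence stems of man6, MAN6 overexpression and wild-type Arabidopsis were profiled by RNA-seq. Per the labels' protocols, total RNA was treated with DNase, complementary DNA was made and fragmented, fragments averaged 400 bases, and libraries were sequenced as paired reads of 100 bases on an Illumina HiSeq instrument. The genome build was TAIR10, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here, and neither is whether reads or read pairs were counted, or how reads in overlapping genes were assigned. The labels list 5 samples, 2 of man6, 2 of MAN6 overexpression and 1 of wild type. The series design speaks of separate overexpression lines, and which of them a value comes from is not stated in the column names.

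The authors deposited 2 comparison tables, 1 per genotype against wild type, and 4 gene sheets. Per the file headers, each comparison table gives for every gene the normalised read count (signal) of wild type and of the other genotype, their mean, a fold change (ratio), a log2 fold change, a p-value and an adjusted p. The deposited sheets repeat the rows of genes higher or lower in each comparison and add the position, name and annotation of the gene. On inspection, the sheets held exactly the genes with an unadjusted p under 0.05, 311 higher and 305 lower for man6 and 326 higher and 471 lower for overexpression. The adjusted p equalled a Benjamini-Hochberg adjustment of the deposited p-value to within 1e-06. The deposited tables carry DESeq in their names, but the version of the authors' test is not given in the sources used here. Each of these tables was normalised separately.

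The normalised counts (signal) that the authors deposited turned out to be whole reads divided by a size factor. In each column 100% of values were whole multiples, within a tolerance of 1e-06, of the smallest value above 0, so the reads were recovered. The wild-type reads were identical in both tables for all 22046 genes they share, and 23014 genes had a read in some library. Totals were 13099443 reads for wild type, 12790841 for man6 and 13161315 for overexpression. A floor of 3 reads stands for 0.229, 0.235 and 0.228 CPM. Log2 fold changes computed from the recovered reads and the deposited scaling equalled the deposited ones to within 1e-06. Folds are given with an exact (Clopper-Pearson) 95% binomial interval on the reads of 2 libraries. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A fold against a library with 0 reads is a lower bound against 3 reads.

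The design, fixed before the data were examined, foresaw edgeR's quasi-likelihood test for counts of each sample, and the authors' adjusted p under 0.05 if only group values were given. With 1 column per group there are no residual degrees of freedom, so no test across replicates was run, and calls are those of the authors' deposited table. "Rose" and "fell" refer to these calls. Between the overexpression and man6 libraries, values were scaled through the shared wild-type column and described by a fold of at least 4 at a mean of at least 100, with no test. As an alternative chosen after seeing the data, edgeR's exact test (edgeR 4.0.16, R 4.3.3) was run on the recovered reads, with the dispersion estimated by treating both libraries as replicates or with an assumed biological coefficient of variation of 0.1, 0.2 or 0.4. Such a test compares these libraries, not the conditions. On simulated data with 200 changed genes among 21752, made from the wild-type reads for the overexpression comparison, the estimated dispersion found 54% of 4-fold and 100% of 16-fold changes at a variation of 0.2. At a variation of 0.4 it found 0% and 39%.

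Gene lists, 26 with 382 genes, were fixed before the data were examined, and 373 of these genes had reads. They cover wall synthesis, hormones, defence, stress, markers of other stem tissues, handling and the clock. Each list was described by its median log2 fold change and the percentile of that median among 10000 random lists of the same size, drawn with matching mean expression in 20 bins. In 100 simulated lists of 15 genes, 4 lay outside the central 95% with no shift and 94 with a shift of 1 on the log2 scale. Those lists held genes drawn at random. Genes of a real list can move together within a library, which this simulation leaves out. Percentiles therefore describe these libraries and do not test the genotype. Members were also counted when adjusted over the list alone (Benjamini-Hochberg on the authors' p-values). Alternative settings were a threshold of 0.01, a 2-fold minimum, an unadjusted p, means of at least 10 or 100, other scalings (total reads, TMM, upper quartile, median centring), pseudocounts of 1 and 10, and rank correlation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

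The rule for named genes was fixed before the data were examined. It takes MAN6 first, then, per comparison, the 8 called genes with the largest change in each direction at a mean of at least 100. Up to 4 called members of each list follow, then genes called in both comparisons. Few list members passed the adjusted test, so members at an unadjusted p under 0.05 were also named in the same order. This extension, and the naming of the other genes called, of CESA7, CESA8, XCP1, XCP2, VSP1 and of the genes named between overexpression and man6, was chosen after the values were seen. Gene symbols come from the RefSeq table of TAIR10.1, which matched 22852 gene IDs. The other 162 were plastid or mitochondrial. For all genes on the sheets that RefSeq holds, the deposited coordinates equalled those in RefSeq. Exons are those of RefSeq's annotation.

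Whether a man6 or overexpression column holds 1 of the labelled samples or both together is not stated in the sources used here, and it is called 1 library throughout. No leave-one-out, paired or batch analysis could be made with 1 column per group.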

Results

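RNA was sequenced from the inflorescence stem of Arabidopsis thaliana plants labelled 3 weeks old, to examine what the endo-beta-mannanase gene MAN6 (AT5G01930) does in cell wall formation. MAN6 encodes an enzyme that cuts mannan, a hemicellulose of the plant cell wall. The labels describe 2 samples of the T-DNA insertion mutant man6, 2 samples that overexpress MAN6 from a transgene and 1 wild-type sample. Values were given for 1 man6 column, 1 overexpression column and 1 wild-type column, and the column names did not say which of the 2 samples of a genotype was meant, or whether a column holds both together. Each column is called a library below. The library totals were 13099443 reads for wild type, 12790841 for man6 and 13161315 for MAN6 overexpression. Reads were found for 21752 genes in wild type, 21848 in man6 and 21344 in the overexpression library. No values were given per replicate, so every comparison is of 1 library with 1 library and has no replicate check. The intervals given with folds are exact 95% intervals for counting error only.

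MAN6 was read 369 times in wild type, 172 times in man6 and 112354 times in the overexpression library, where it took 0.854% of all reads. The overexpression library was 318-fold above wild type (interval 287 to 353). This was the largest rise among genes with reads in both libraries, and the authors' deposited table gave it an adjusted p of 2.21e-08. The man6 library, whose label calls the genotype a MAN6 knockout, held 0.501 times the wild-type level (interval 0.416 to 0.602). The authors' deposited table gave that difference an unadjusted p of 0.192 and an adjusted p of 1, so MAN6 was lower in man6 without passing the test. Which part of the MAN6 transcript lies on either side of the T-DNA insertion is not given in the sources used here, so these reads do not show how much intact transcript the mutant made.

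MAN6 lies on the reverse strand of chromosome 5 from 361081 to 362901 (TAIR10). STN8 (AT5G01920), which encodes a protein kinase of the chloroplast thylakoid, lies on the forward strand from 359107 to 361310. In the RefSeq annotation of TAIR10.1, exon 5 of STN8, an untranslated exon from 361163 to 361310, falls within exon 5 of MAN6, which spans 361081 to 361627. Of these 148 shared bases, 122 are coding in MAN6 and 26 are in its 3′ untranslated region. STN8 was read 358 times in wild type, 389 times in man6 and 17634 times in the overexpression library, 51.4-fold above wild type (interval 46.3 to 57.2), with an adjusted p of 2.72e-04 in the authors' deposited table. The sources used here do not say whether the library protocol kept the strand. Without strand, reads of a gene and of its antisense partner cannot be told apart, so the value of STN8 is uncertain.

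**Figure D1:**
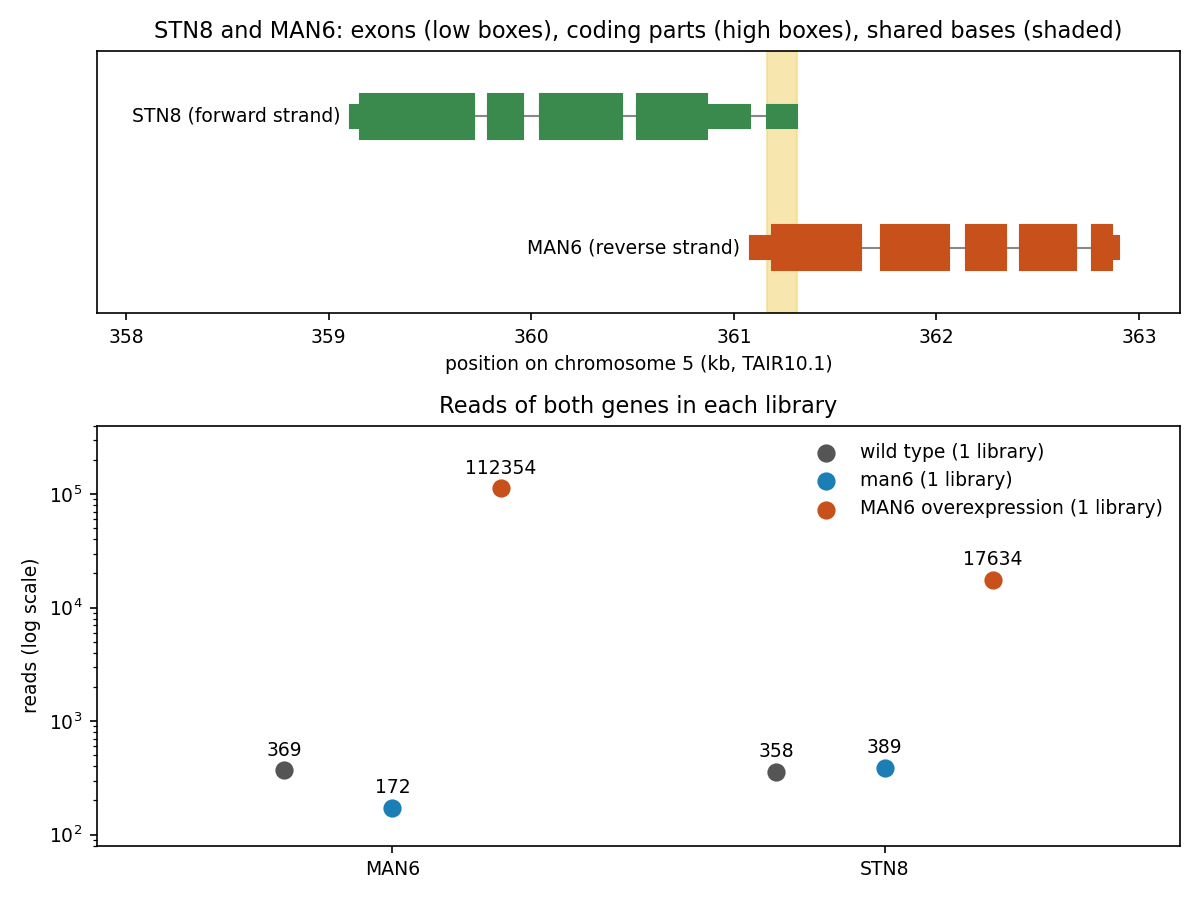
The upper panel maps the exons of STN8 and MAN6 along chromosome 5 (kb), with coding parts as high boxes and the 148 shared bases shaded. The lower panel gives the reads of both genes in each library on a log scale, 1 point per library: 112354 MAN6 and 17634 STN8 reads in the overexpression library against 369 and 358 in wild type.

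Setting man6 against wild type asks which stem genes differ when MAN6 carries an insertion. In the man6 library, 15 genes passed the test. By list medians, heat shock genes were lower, photosynthesis, touch, auxin and xyloglucan genes were higher, and xylan, mannan and lignin genes were lower by less. By the authors' deposited table, 7 genes rose and 8 fell of 22640 tested. Superoxide dismutase CSD2 rose 11.1-fold (interval 9.80 to 12.6), the chlorophyll-binding protein gene LHB1B1 rose 21.6-fold (interval 19.1 to 24.4), and the heat shock chaperone gene HSP90.1 fell 8.84-fold (interval 8.33 to 9.38). The gene pair MRD1 and HEI10 on chromosome 1 fell 31.9-fold (interval 23.1 to 45.3) and 40.6-fold (interval 20.4 to 94.8).

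The largest rise was that of AT1G64795, which encodes an uncharacterized protein, with 763 reads in man6 and 1 read in each of the other libraries, an 820-fold ratio with a counting interval of 147 to 32430. Its annotation overlaps that of AT1G64790 by 270 bases, which was read 905 times in wild type, 1666 times in man6 and 1019 times in the overexpression library. EARLI1, which encodes a lipid-transfer-like protein, rose 18.4-fold (interval 10 to 37.4). AT1G36060, annotated as an integrase-type DNA-binding protein, rose 18-fold (interval 10.9 to 31.9), and the uncharacterized AT1G13670 rose 15.5-fold (interval 9.48 to 27.0). AT5G50562 had no read in wild type and 67 in man6, at least 24.0-fold higher against a floor of 3 reads. Among the falls, AT3G28270 was 13.7-fold lower and AT3G28220, a TRAF-like gene, 13.3-fold lower. PGL5, which encodes a 6-phosphogluconolactonase, fell 9.36-fold, and AT5G48570, an FKBP-type peptidyl-prolyl isomerase gene, fell 9.44-fold. AT1G27565 was read 78 times in wild type and in neither of the other libraries, at least 24.2-fold lower in man6. MRD1 (chromosome 1, 19963047 to 19964712, reverse strand) and HEI10 (19963267 to 19966952, forward strand) share 1446 bases on opposite strands, so their reads cannot be assigned to either gene with certainty.

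Heat shock genes had the lowest median of the lists in man6, a log2 fold change of -2.69 (percentile 0 among 10000 random lists). Of 7 members, HSP90.1 fell, and 6 were lower at an unadjusted p under 0.05 in the authors' deposited table, all 6 of which passed when adjusted over the list alone. Values in man6 against wild type were 1884 and 15001 reads for HSP70, 129 and 895 for the heat shock transcription factor HSFA2, and 10 and 98 for the small heat shock protein gene HSP17.6II. The 20 photosynthesis genes, a list fixed as a marker of green tissue, were all above wild type, with a median of 1.23 (percentile 100). None passed the adjusted test, 1 passed when adjusted over the list alone, and 9 were higher at an unadjusted p under 0.05 in the authors' deposited table. LHCB1.1 had 3282 reads in man6 against 688, LHCB3 had 10148 against 2744, and the Rubisco small subunit gene RBCS2B had 1121 against 308.

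The 7 touch and wounding genes were all above wild type in man6, with a median of 1.66 (percentile 100). By the authors' deposited table none passed the adjusted test and 5 were higher at an unadjusted p under 0.05, 4 of them when adjusted over the list alone. The ethylene response factor genes ERF1 and ERF6 had 464 and 374 reads against 90 and 84 in wild type, and the zinc finger gene ZAT10 had 1588 against 539. Of the 13 jasmonate response genes, 10 were above wild type (median 0.58, percentile 98.1, or 97.2 at a mean of at least 10), but LOX2 and VSP1 were lower, with 132 reads against 652 and 447 against 1922. Auxin response genes had a median of 0.86 (percentile 100), with 20 of 22 measured members above wild type. Of these, GH3.3, which conjugates auxin to amino acids, had 367 reads against 45. Xyloglucan endotransglucosylase genes, which remodel the wall during growth, had a median of 1.2 (percentile 100), with 16 of 18 above wild type. XTH24 had 12175 reads against 3670, and XTH9 had 303 against 96. No member of the jasmonate, auxin or xyloglucan lists passed the adjusted test.

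Secondary wall lists lay below wild type in man6, by less than 2-fold at their medians. The medians were -0.70 for xylan synthesis (19 of 21 genes lower, percentile 0), -0.77 for mannan synthesis and turnover (13 of 16, percentile 0.01) and -0.78 for lignin polymerisation (7 of 10, percentile 0.13). They were -0.53 for monolignol synthesis (14 of 16, percentile 0.13) and -0.47 for secondary wall transcription factors (22 of 33, percentile 0.04). None of these members passed the adjusted test. At an unadjusted p under 0.05 in the authors' deposited table, lower members were the glucomannan synthase gene CSLA9, with 1348 reads against 5220, MSR1 with 364 against 1350, and the wall transcription factor gene NST1 with 360 against 1170. Secondary wall cellulose genes had a median of -0.33 (percentile 3.9), primary wall cellulose genes -0.38 (percentile 3.29) and xylem cell death genes 0.36 (percentile 92.6). The cellulose synthase genes CESA4, CESA7 and CESA8 were at 5217, 7746 and 9081 reads in man6 against 6921, 8750 and 12540 in wild type. The circadian clock list had a median of 0.45 (percentile 97.7, or 96.2 with a pseudocount of 10), led by TOC1 with 3748 reads against 1256.

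The remaining lists lay within the central 95% of random lists in man6. Their medians were 0.13 for expansins (-0.01 with genes at 0 set to their bound), 0.12 for pectin genes, -0.29 for brassinosteroid genes, 0.43 for gibberellin genes and 0.07 for cambium genes. They were -0.11 for phloem markers, 0.37 for the cell cycle, -0.26 for epidermis and cuticle and 0.60 for flower and pollen markers (0.23 with genes at 0 set to their bound). Brassinosteroid and cell cycle genes lay outside that range at a mean of at least 10 (-0.67 and 0.53), epidermis genes at a mean of at least 100 (-0.42) and gibberellin genes with a pseudocount of 10 (0.38). They were -0.37 for salicylic acid and pathogen response, which turned to 0.73 (percentile 99.9) among members with a mean of at least 100, and 0.30 for abscisic acid and cold response. Within the expansin list, EXLA3 and EXLA1 were higher, with 868 reads against 164 and 3212 against 805, and 2 members passed when adjusted over the list alone. Within the brassinosteroid list, BR6OX2 was lower, with 10 reads against 137. Within the pathogen list, PR2 and PAD3 were lower, with 333 reads against 2927 and 12 against 159, and WRKY40 was higher, with 5298 against 923. The calls of man6 genes are the authors' own, from a test that had 1 library on each side. At an unadjusted p under 0.05, the threshold of the authors' gene sheets, the count was 616.

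Setting MAN6 overexpression against wild type asks which stem genes differ when the mannanase is made in excess. By list medians, genes of secondary wall formation were lower in the overexpression library, and photosynthesis genes and genes of salicylic acid and pathogen response were higher. By the authors' deposited table, 27 genes rose and 16 fell of 22420 tested. MYB103, a transcription factor of secondary wall formation, fell 71.3-fold (interval 38.5 to 149), from 744 reads to 10. CSLA9, which makes the glucomannan backbone, fell 32.3-fold (interval 27.5 to 38.1), from 5220 reads to 155. The pathogenesis-related gene PR5 rose 19.4-fold (interval 17.0 to 22.3), and PR1 went from no read to 161, at least 56.0-fold higher. ASN1, an asparagine synthetase gene, rose 15.6-fold (interval 15 to 16.3), from 2530 reads to 37805.

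At a mean normalised count of at least 100, the largest rise after MAN6 was that of the defensin-like gene PDF1.4, at 101-fold (interval 39.0 to 372). It was followed by the granulin cysteine protease gene AT3G19390 at 67.5-fold (interval 48.9 to 96.2), STN8, the lectin gene AT5G03350 at 45.8-fold (interval 30.6 to 71.9) and the cupredoxin gene AT2G15780 at 43.0-fold (interval 22.4 to 94.9). The ankyrin gene ANK rose 39.4-fold (interval 21.2 to 82.8), and GAT1_2.1, which encodes a glutamine amidotransferase, rose 35.9-fold (interval 26.9 to 49.1). DIN2, a dark-inducible beta-glucosidase gene, had no read in wild type and 143 in the overexpression library, at least 49.8-fold higher. At the same mean, the largest fall was that of MRD1, from 1302 reads to 5, or 249-fold (interval 107 to 770). ARGOS, an auxin-regulated gene of organ size, fell 85.2-fold (interval 41.1 to 213), and AT3G22275, annotated as a jasmonate ZIM-domain protein, fell 68.2-fold (interval 32.8 to 170). MYB24, a stamen transcription factor gene, fell 40-fold (interval 19.2 to 100.3), the nucleoside triphosphatase gene AT3G28600 fell 31.8-fold, and AT4G24350, of the phosphorylase superfamily, fell 30.7-fold. Below that mean, AT4G20820 rose from 4 reads to 176, AT3G02480, annotated as a late embryogenesis abundant protein, fell from 143 reads to 1, and LEA7 went from 103 reads to 0, at least 32.9-fold lower.

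Secondary wall transcription factors had the lowest median of the lists in the overexpression library, -2.21 (percentile 0), with 30 of 33 members below wild type. By the authors' deposited table MYB103 fell, 11 members were lower at an unadjusted p under 0.05, and 7 passed when adjusted over the list alone. MYB85 had 51 reads against 620, MYB7 had 57 against 644 and MYB43 had 74 against 611. Secondary wall cellulose and assembly genes had a median of -2.08 (percentile 0), with 9 of 10 below wild type. None passed the adjusted test, 6 were lower at an unadjusted p under 0.05 in the authors' deposited table, and 5 passed when adjusted over the list alone. The fasciclin-like arabinogalactan protein genes FLA12 and FLA11 had 186 and 396 reads against 1975 and 4130, and the COBRA-like gene COBL4 had 341 against 2214. CESA4, CESA7 and CESA8 had 1192, 2497 and 4334 reads against 6921, 8750 and 12540 in wild type.

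Xylan genes had a median of -1.37 (percentile 0), with 19 of 21 below wild type and 7 lower at an unadjusted p under 0.05 in the authors' deposited table, 2 of them when adjusted over the list alone. The xylan methyltransferase gene GXMT1 had 47 reads against 426, GAUT12 had 241 against 1923 and IRX15 had 712 against 3984. Mannan genes had a median of -1.10 (percentile 0). Besides CSLA9, which fell, CSLA10 had 104 reads against 1062 and MSR1 had 222 against 1350, and these 3 passed when adjusted over the list alone. Lignin polymerisation genes had a median of -1.41 (percentile 0.01). The peroxidase gene PRX64 had 88 reads against 1173 and the laccase gene LAC12 had 21 against 189, while PRX72 was higher, with 57 against 1. Monolignol genes had a median of -0.98 (percentile 0.01), with 15 of 16 below wild type. PAL3 was the exception, with 530 reads against 72. Primary wall cellulose genes had a median of -0.65 (percentile 1.09), with all 11 members below wild type, and CC2 was the lowest, with 45 reads against 345.

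Markers of other tissues stood beside these groups as follows. Xylem cell death genes had a median of -0.76 (percentile 1.56), with 5 of 7 below wild type, and of -0.11 (percentile 30.8) among the 5 members with a mean of at least 100. In that list the xylem proteases XCP1 and XCP2 were at 351 and 2471 reads against 355 and 2787. Cambium genes had a median of -1.03 (percentile 0.04), with WOX4 at 8 reads against 86. Photosynthesis genes had a median of 1.31 (percentile 100), all 20 above wild type, 6 of them at an unadjusted p under 0.05 in the authors' deposited table and 2 when adjusted over the list alone. The Rubisco small subunit genes RBCS1B and RBCS2B had 454 and 1887 reads against 55 and 308. These genes, the light-harvesting genes and the small heat shock genes belong to families of similar copies whose reads the authors' counting could split between members. Phloem markers had a median of -0.23, epidermis and cuticle genes -0.05, and flower and pollen markers -1.47, all within the central 95% of random lists as deposited. Of 14 flower and pollen markers measured, 9 had no read in 1 of the 2 libraries, and with those at their bound the median was -1.42. This list lay outside the central 95% at a mean of at least 10 (percentile 1.07).

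Of the 13 genes of salicylic acid and pathogen response, 11 were above wild type, with a median of 1.82 (percentile 100). PR1 and PR5 rose by the authors' deposited table, 6 members were higher at an unadjusted p under 0.05, and 4 passed when adjusted over the list alone. PAD4, a lipase-like regulator of defence, had 792 reads against 102, and PR2, a glucanase gene, had 14765 against 2927. Jasmonate response genes had a median of -1.42 (percentile 0.01), or -1.59 with the gene at 0 in 1 library set to its bound. None passed the adjusted test. JAZ5, JAZ7 and LOX4 had 481, 323 and 298 reads against 3572, 2303 and 1680, while LOX2 and VSP1 were above wild type, with 3187 reads against 652 and 8543 against 1922. Auxin response genes had a median of -0.94 (percentile 0.01), with 17 of 21 below wild type. IAA19 had 31 reads against 279. Touch and wounding genes had a median of -0.86 (percentile 1.69), or -0.47 (percentile 11.5) at a mean of at least 100, abscisic acid and cold genes -1.18 (percentile 0.49) and expansins -0.96 (percentile 0.16).

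Heat shock genes went both ways in the overexpression library, with a median of -0.22 (percentile 17.4). HSP18.2 and HSP17.6II had 649 and 951 reads against 54 and 98, and HSP70 had 3324 against 15001. The remaining lists lay within the central 95% of random lists. Their medians were 0.35 for xyloglucan endotransglucosylases (0.52 with the gene at 0 set to its bound), -0.28 for pectin genes, 0.10 for brassinosteroid genes, 0.03 for gibberellin genes (0.51 with the gene at 0 set to its bound and -0.51 at a mean of at least 100), -0.21 for the cell cycle (0.11 at a mean of at least 10) and 0.25 for the circadian clock. GA2OX6 and GA2OX8, which inactivate gibberellin, were lower, with 172 and 206 reads against 899 and 883. The calls in the overexpression library are the authors' own, from a test that had 1 library on each side. At an unadjusted p under 0.05, the threshold of their gene sheets, the count was 797, with more genes lower (471) than higher (326).

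**Figure D2:**
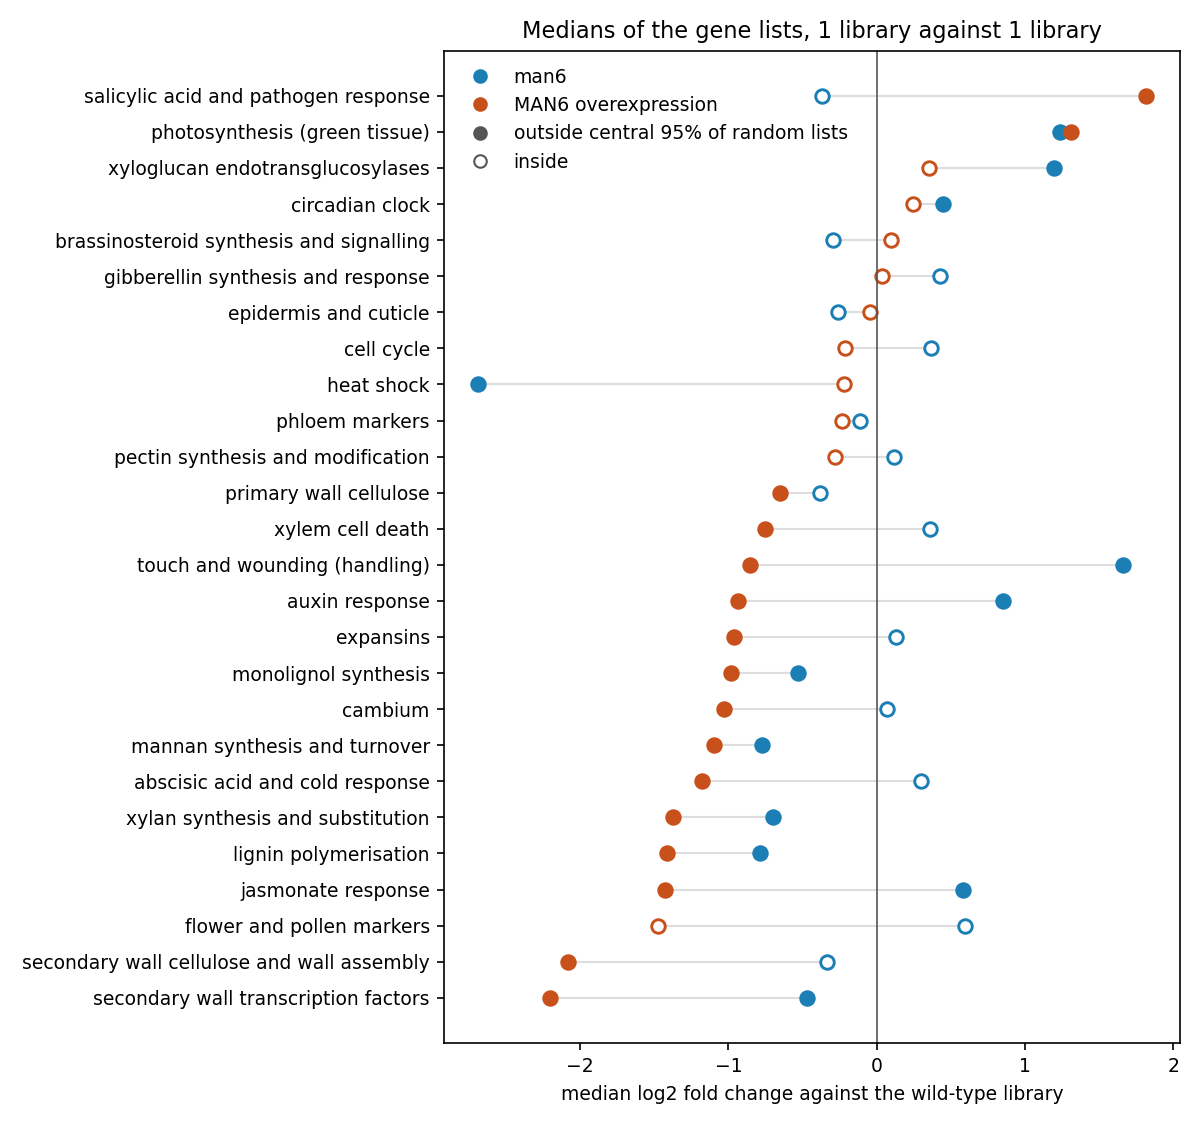
Median log2 fold change against the wild-type library of each of the 26 gene lists, for man6 (blue) and MAN6 overexpression (orange), each from 1 library against 1 library. Filled points lie outside the central 95% of 10000 random lists matched on expression, which holds for 12 lists in man6 and 16 in the overexpression library; secondary wall transcription factors are at -0.47 in man6 and -2.21 in overexpression, and heat shock genes at -2.69 in man6 and -0.22 in overexpression.

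The overexpression and man6 libraries were set against each other through their common wild-type column, with no test. By list medians, genes of salicylic acid and pathogen response were higher in the overexpression library than in man6. Auxin, touch, jasmonate and secondary wall genes were lower. Among 13391 genes with a mean normalised read count of at least 100, 628 differed by at least 4-fold, 216 higher and 412 lower in the overexpression library. MAN6 was 634-fold higher (interval 546 to 741), and PR5 was 74.2-fold higher (interval 57.0 to 98.4). The defence gene AIG1 had 280 reads against 0 in man6, and the lectin gene AT5G03350 had 1054 against 5. The auxin-conjugating gene GH3.3 had 5 reads against 367, a 75.6-fold lower level, and ERF1 had 10 against 464, a 47.8-fold lower level.

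List medians between these libraries were -1.88 for auxin response (all 22 measured genes lower, percentile 0), -2.52 for touch and wounding (all 7 lower, percentile 0) and -1.52 for jasmonate response (10 of 13 lower, percentile 0.03). They were -1.75 for secondary wall cellulose (9 of 10 lower, percentile 0), -1.52 for secondary wall transcription factors (32 of 33 lower, percentile 0) and -0.93 for xylan (17 of 21 lower, percentile 0). Pathogen response genes had a median of 2.33 (10 of 13 higher, percentile 100) and heat shock genes 2.04 (all 7 higher, percentile 100). Photosynthesis genes, above wild type in both libraries, had a median of 0.15 between them (percentile 80.7). Folds between these libraries carry no test of their own.

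Both libraries shared few calls. By the authors' deposited table, CSD2 and LHB1B1 rose in both libraries and MRD1 fell in both. CSD2 had 270 reads in wild type, 2790 in man6 and 3661 in the overexpression library, and LHB1B1 had 274, 5493 and 4667. Independent lists of those sizes would share 0.00826 risen and 0.00581 fallen genes, and a simulation with no effect, a shared wild-type library and an assumed variation of 0.4 gave 1.95 and 0.2. No gene passed the adjusted test in opposite directions. HEI10, at 349, 8 and 19 reads, fell in man6 and had an adjusted p of 0.0831 in the overexpression comparison of the authors' deposited table.

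At an unadjusted p under 0.05, 60 genes were higher in both libraries and 42 lower in both. Independent lists of those sizes would share 4.56 and 6.52 genes, and simulations with no effect and a shared wild-type library gave 88.8 and 34.5 with an assumed variation of 0.4, 66.3 and 43.5 with 0.2, and 53.4 and 59.8 with counting error alone. A further 13 genes were higher in man6 and lower in the overexpression library, and 13 the reverse, where these simulations gave at most 0.05. Each simulation gave every gene the same variation, so it does not show how many such genes would arise if some genes varied more. Across 20350 genes with reads in all libraries, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson correlation of 0.287 and a Spearman correlation of 0.31. With no effect and a shared wild-type library, the simulated Pearson correlation was 0.503 with counting error alone and 0.5 with an assumed biological variation of 0.4. The covariance was 0.243, against simulated values of 0.0796 with counting error alone, 0.164 with an assumed variation of 0.2 and 0.433 with 0.4. Part of any excess may come from the shared wild-type library, which could not be split.

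**Figure D3:**
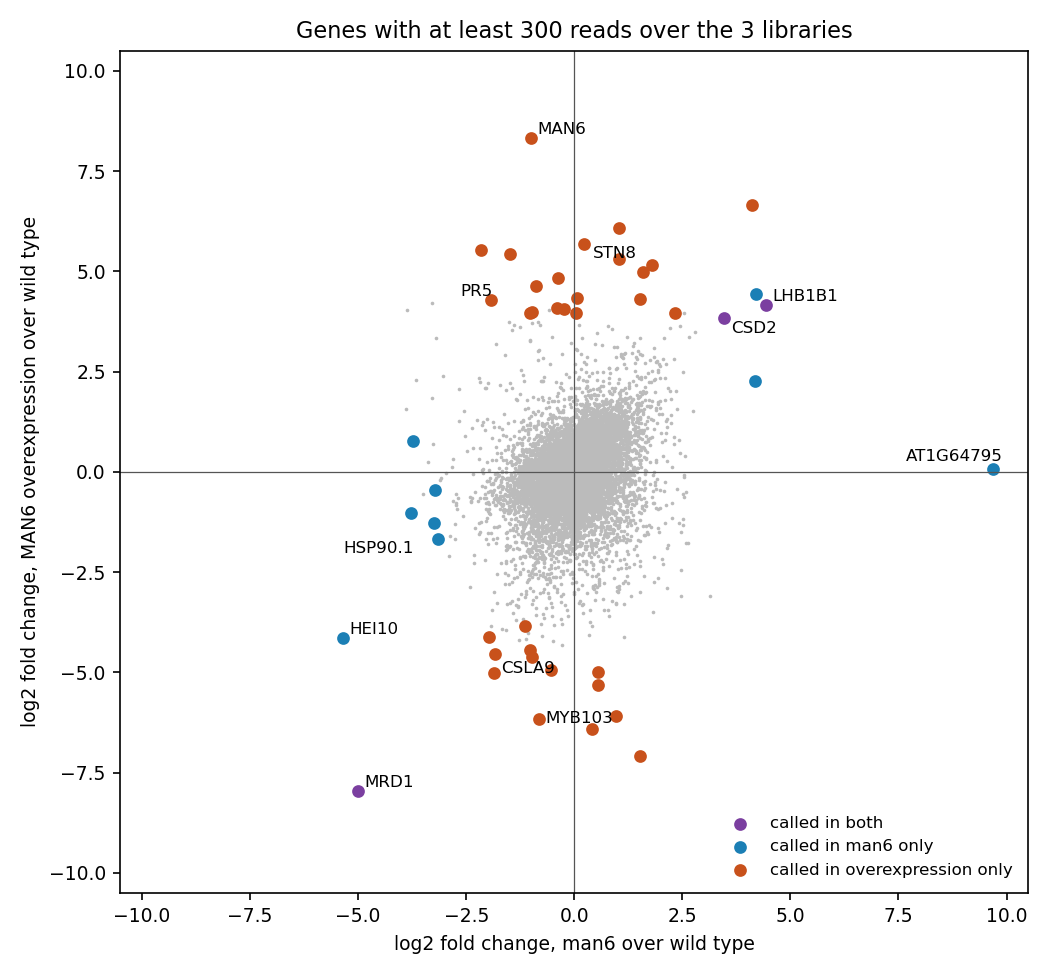
Log2 fold change of each gene with at least 300 reads over the 3 libraries, man6 over wild type (x axis) against MAN6 overexpression over wild type (y axis). Colours mark genes called in the authors' deposited table; MRD1 lies at -4.99 and -7.96, CSD2 at 3.47 and 3.82, and MAN6 at -1 and 8.31.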

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

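The tests of explanations in this part were chosen after the results they bear on were seen, while the list medians were planned. The genes and lists in the next 2 paragraphs stand out because the man6 library and the overexpression library lay on opposite sides of wild type. The difference between the libraries was not tested for any of them, and each side is 1 library. In all, 26 genes had an unadjusted p under 0.05 in both comparisons of the authors' deposited table with opposite signs.

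Some genes were above wild type in the overexpression library and below it in man6. AT3G47380, annotated in the invertase and pectin methylesterase inhibitor family, had 735 reads in the overexpression library, 47 in wild type and 3 in man6, a ratio of 238 between overexpression and man6 (counting interval 81.1 to 1157). AT3G47480, an EF-hand gene, had 264, 30 and 2 reads, a ratio of 128 (counting interval 35.1 to 1064). HSP17.6II was 92.4-fold and PR2 43.1-fold higher in the overexpression library than in man6. Other genes lay the other way round. ERF1 was 47.8-fold higher in man6 than in the overexpression library, RAS1 30.3-fold, ORA59, an ethylene and jasmonate response factor gene, 33.0-fold, and the kinase gene MAPKKK19 18.3-fold. ORA59 had 898 reads in man6, 217 in wild type and 28 in the overexpression library.

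The medians of 3 lists stood on opposite sides of wild type as well and outside the central 95% of random lists in both comparisons, with members that went either way. Other lists also had medians of opposite sign, but not outside that range in both comparisons. Among these was pathogen response, at -0.37 in man6 and 1.82 in overexpression. Its man6 median turned above wild type among members with a mean of at least 100, so its sign in man6 depends on the setting. Jasmonate genes were 10 higher and 3 lower in man6 and 4 higher and 9 lower in overexpression, and 2 of 7 touch genes were above wild type in overexpression. The jasmonate median in man6 and the touch median in overexpression (-0.47 at a mean of at least 100) lay inside the central 95% of random lists under some settings. The medians of the lists between overexpression and man6 were -1.88 for auxin response, -1.52 for jasmonate response and -2.52 for touch and wounding.

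Touch and wounding genes respond to handling within minutes, but their median of -2.52 is the pattern itself and does not test handling. Handling at harvest and genotype cannot be told apart with 1 library each. A different time of day may also contribute. Morning and evening clock genes would then differ in opposite directions, but TOC1 and CCA1 were both lower in the overexpression library than in man6, by log2 ratios of -0.60 and -2.21. The 12 clock genes of the list went both ways between these libraries, 5 higher and 7 lower in overexpression, from -2.21 to 1.66. That pair therefore does not decide on time of day. The variation between libraries was not measured, so time of day stays open.

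Besides these, STN8 was 51.4-fold above wild type in the overexpression library, and reads of the MAN6 transcript counted for STN8 are a candidate explanation. The excess of STN8 reads was 15.4% of the excess of MAN6 reads. The shared exon holds 9.94% of the MAN6 transcript; of the 100-base reads that it can give, 16.5% would touch that exon and 3.53% would lie within it, and 21.1% of 400-base fragments would touch it. The excess is near the share of reads that touch the exon and above the share within it. This explanation therefore needs a counting rule that accepts partial overlap, and the rule is not given in the sources used here. The shares were computed on the annotated MAN6 transcript and would differ if the transgene carries only part of it. The other 10 genes within 20 kb with at least 20 reads had a median log2 fold change of 0.11. That median argues against activation of the whole neighbourhood, although single genes ran from -1.96 to 1.45. Whether STN8 itself also changed stays open, since strand was not used here.

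Secondary wall genes were lower in the overexpression library, with a median of -2.08 for the cellulose and wall assembly list. The tables argue against scaling as the whole cause and do not decide on a lower share of xylem. That median moved by -0.0542, to -2.14, when total reads without those of MAN6 and STN8 replaced the deposited scaling. The move includes the change of scaling method, so it does not isolate the effect of the MAN6 transcript. MAN6 took only 0.854% of the overexpression reads, so leaving it out could move the scaling little. With upper quartile scaling the median was -2.12. A lower share of xylem would lower all abundant xylem transcripts alike. None of the 7 xylem cell death genes was below -1.5 and the lowest was at -1.06. That cutoff was chosen after the values were seen. The cell death genes were lower too, with a median of -0.76, but of only -0.11 among the 5 members with a mean of at least 100. The wall list itself ran from -3.35 to 0.149. A lower share of part of the xylem therefore stays open. Younger, still elongating tissue would raise expansins and cell cycle genes: expansins were lower, with a median of -0.96, but cell cycle genes went both ways, 10 higher and 11 lower, with a median of -0.21 that turned to 0.11 at a mean of at least 10, so this stays open beside an untested effect of MAN6 overexpression.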

How the results depend on the processing

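The edgeR exact tests, and the 8-fold minimum and the mean of at least 500 between overexpression and man6, were chosen after seeing the data, and the other settings before. No paired analysis was possible because the labels pair no samples. Quasi-likelihood, DESeq2 and limma-voom fits, leaving out a replicate, and block terms could not be run, since 1 column per group leaves no residual degrees of freedom. For man6 against wild type, where 15 genes were called, the count was 4 at an adjusted p under 0.01 and 616 at an unadjusted p under 0.05. With edgeR's exact test and adjusted p under 0.05 it was 32 with the dispersion estimated from the libraries, and 5145, 967 and 7 with an assumed variation of 0.1, 0.2 and 0.4. For overexpression against wild type, where 43 genes were called, these counts were 20, 797, 120, 6823, 2500 and 180 in the same order; more of the called genes were higher than lower (27 and 16), but the reverse held at the unadjusted p and in all edgeR tests. The counts depend on the variation assumed between plants, which 1 library per group does not measure. A 2-fold minimum, a mean of at least 10 or 100, and leaving out genes at 0 gave 13 to 15 genes for man6 and 36 to 43 for overexpression. Between overexpression and man6, where 628 genes differed by 4-fold, the count was 2501 at 2-fold, 220 at 8-fold, 1283 with means of at least 10 and 267 with means of at least 500, where the setting itself admits more or fewer genes.

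Of the list medians under other means and pseudocounts, 281 kept their direction and their side of the central 95% of random lists, 10 moved outside it, 8 moved inside it and 13 reversed; the cause was not tested. Other scalings shift all genes alike, so a list's percentile cannot change under them. The reversals came from medians inside the central 95%, and 1 ended outside it. With means of at least 100, the man6 medians turned to 0.73 for pathogen response (that exception), -0.23 for pectin, 0.0816 for brassinosteroid, -0.000991 for gibberellin, -0.0803 for cambium, -0.0872 for flower and pollen and -0.0276 for abscisic acid genes, and the overexpression medians to -0.0221 for brassinosteroid, -0.51 for gibberellin and 0.0681 for cell cycle genes. With means of at least 10 they turned to -0.15 for expansins in man6, and to 0.11 for cell cycle and 0.0206 for epidermis genes in overexpression. The constant shift of upper quartile scaling turned gibberellin genes in overexpression to -0.00356. Medians that moved inside were jasmonate (3 settings) and clock genes in man6, xylem cell death and touch genes in overexpression, and xylem cell death and xyloglucan genes between overexpression and man6. Those that moved outside were brassinosteroid, gibberellin, cell cycle and epidermis genes in man6, xyloglucan and flower genes (3 settings) in overexpression, and cell cycle and flower genes between both. MAN6 in man6 ranged from -1.07 to -0.96 and in overexpression from 8.24 to 8.32 on the log2 scale under the other scalings. The Pearson correlation of both comparisons was 0.268 and 0.283 at means of at least 10 and 100, and the rank correlation 0.31 over all genes and 0.352 at a mean of at least 100. The floor of 3 reads, or about 0.23 CPM, limits what can be said of genes with few reads, among them most flower and pollen markers.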

Other observations

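The low-sugar and copper tests were chosen before their results were seen, the use of the photosynthesis list after, and both gene groups were picked after DIN2, GAT1_2.1, ASN1, DIN10 and CSD2 had been seen. Genes that respond to low sugar or darkness were higher in the overexpression library. SEN1, a senescence and darkness gene, had 909 reads in wild type, 3906 in man6 and 10408 in overexpression. Over all 20 genes of a low-sugar list, the median log2 fold change was 1.95 in overexpression, with all 20 above wild type, and 1.07 in man6, with 18 above.

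A hypothesis is that the sampled overexpression stem was in a low-sugar state. Without the 4 genes of this list seen before (DIN2, GAT1_2.1, ASN1 and DIN10), the remaining 16 had a median of 1.63 in the overexpression library, with all 16 above wild type, at percentile 100 of random lists. They were read in the same library as those 4 and may move with them, so they are not an independent check. The same 16 genes had a median of 0.89 in man6 (percentile 100) and of 0.53 between overexpression and man6 (percentile 99.6). Photosynthesis genes, which darkness lowers, had a median of 1.31 in the overexpression library, with all 20 above wild type, which goes against darkness. With 1 library each, a state of the genotype and a larger share of green tissue stay open. So do the growth or harvest conditions of the overexpression sample, or of the wild-type sample that both comparisons share.

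The copper enzymes CSD1 and CSD2 and their chaperone CCS were higher, and the iron enzyme FSD1 lower, in both libraries than in wild type. CSD1 had 828 reads in wild type, 2021 in man6 and 7311 in overexpression, CCS had 394, 980 and 1684, and FSD1 had 9470, 4063 and 1101. A hypothesis is that the wild-type plant had a lower copper supply, which lowers CSD1, CSD2 and CCS through miR398 and raises FSD1. The smallest of these changes in the predicted direction, that of FSD1 in man6, was 1.12 on the log2 scale, so all 3 genes tested went the predicted way in both libraries. CSD1 and CCS were also higher, and FSD1 lower, in overexpression than in man6. A lower copper supply of the wild-type plant alone does not account for that difference. COPT2, the other gene named for this test, had no reads, and copper supply and genotype cannot be told apart with 1 wild-type library.

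AT1G27565 was read 78 times in wild type and 0 times in both other libraries. AT1G64795 was read 763 times in man6 and 1 time in wild type. The overlapping genes MRD1 and HEI10 were read 1302 and 349 times in wild type, 38 and 8 times in man6, and 5 and 19 times in overexpression. Of the called genes, 5 in man6 and 10 in overexpression overlap another gene with reads.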
